A study of Rattus norvegicus with 2 samples.

How the data were processed

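C6 is an established rat glioma cell line that is widely used as a model of glial tumours. Trimethylation of lysine 4 on histone H3 (H3K4me3) is a histone mark found mainly at the promoters of active and poised genes. Chromatin immunoprecipitation sequencing (ChIP-seq) sequences the DNA fragments that an antibody against the mark pulls down, and input DNA is chromatin from the same kind of cells without the antibody step. Per the labels' protocols, C6 cells were grown in medium with 10% fetal bovine serum to 90% confluence and fixed with 1% formaldehyde, and chromatin was sonicated to an average of 300 bp. H3K4me3 was precipitated with 1 µg of antibody. The labels conflict on the later steps. The protocol speaks of ChIP-chip, the array form of the method, and of an Illumina kit, while the title and platform name SOLiD ChIP-seq. There was 1 H3K4me3 library and 1 input library. The labels give no replicate, no second cell line and no treatment.

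The data analysed here are 1 peak list of the H3K4me3 library. Per the file header, the authors called the peaks with MACS on the H3K4me3 library against the input library, and the submitters' processing notes name the genome build rn4. The MACS version, its settings, the aligner and the read numbers are not given in the sources used here, so the sequencing depth behind each peak is unknown. Each deposited line holds a chromosome, a start, an end, a peak name and a score, with no read count, fold enrichment, summit or gene name. The deposited score runs from 50 to 3233.06. The highest deposited score equals 10 times the negative base-10 logarithm of the smallest positive number that a double-precision value holds, which is also 3233.06. The score was therefore read as 10 times the negative base-10 logarithm of the p-value of a peak. It is the authors' own value throughout.

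The input library has no values of its own in the peak list and entered only through the authors' peak calling. With 1 library there is no replicate error, so no test between groups was made and no p-value between conditions is given. Intervals are 95% intervals that cover counting error only. Shares of peaks have exact Clopper-Pearson intervals, and numbers of peaks per chromosome have exact Poisson intervals. Where a count was 0, the upper limit of its share was set at 3 counts of the total. This is a one-sided limit and lies below that of an exact two-sided interval. PCR copies and peaks that share an enriched region are not independent, so these intervals are too narrow as a measure of repeatability.

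Peak widths, the bases covered, the Spearman and Pearson correlations of width and score across peaks, and the gaps between neighbouring peaks were computed with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1. Figures were drawn with matplotlib 3.10.9. Starts are printed counting from 1. Lengths of the rn4 chromosomes were not used here, so the density of peaks was taken over the span from the first to the last peak of each chromosome, and the share of bases covered over the sum of these spans. Closeness of peaks was measured as the share of peaks with another peak within 2 kb. It was set against 100 random placements of the same peak widths within the same chromosome span, with overlaps allowed. For a view by enriched region, peaks no more than 1 kb apart were joined. These steps were tested on simulated peaks with planted pairs, where the planted share and number of regions were recovered. The simulated peaks had equal widths and even spacing, unlike the listed peaks, so this checked the code alone. A fit of 1 score factor, used in the closing observations, was tested on 20 draws of 629 simulated scores per factor. A true factor of 0.5 came back with a median of 0.50 (range 0.44 to 0.58), and a true factor of 1 with a median of 0.99 (range 0.93 to 1).

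Before the data were examined, the following were fixed: the measures, the alternatives, and the rule for named items, which are the 10 widest peaks and the 10 peaks with the highest score, with ties broken by width, chromosome and start. The alternatives were a stricter threshold at the median score, joining of peaks up to 1 kb apart, a minimum width of 500 bp, and numbered chromosomes and X only. The classes of peak width, the scores of joined regions and their shufflings were not among the fixed measures. A covered share had been planned only for known chromosome lengths, so the share of the spans departs from the plan. Overlap of peaks with transcription start sites and with gene lists fixed beforehand had been planned for the case that gene positions of the same build could be used. The gene table used for names is on another assembly, GRCr8, and coordinates were not converted between builds. Peaks are therefore named by position only, and promoters and gene groups were not analysed here.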

Results

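H3K4me3 was mapped in C6 rat glioma cells with 1 ChIP library, and the authors' peak list against the 1 input library was analysed to describe where in the rn4 genome the mark was enriched, how wide the enriched stretches were and how they were spaced. The list held 30172 peaks on 21 chromosomes, the 20 autosomes and X. There was no replicate, so each value below describes this library alone. Peaks did not overlap one another and together covered 42.2 Mb. This was 1.57% of the 2688 Mb between the first and last peak of the chromosomes.

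Most H3K4me3 peaks were short, and the median score was higher in each wider class of peaks. The median width was 1048 bp, with quartiles of 704 and 1751 bp and extremes of 176 and 14151 bp. Among the 15086 peaks at or above the median score the median width was 1718 bp. The score had a median of 185.6 and quartiles of 75 and 637.6. Of all peaks, 10553 scored under 100, a share of 35.0% with a Clopper-Pearson interval of 34.4 to 35.5%. Width and score rose together across peaks, with a Spearman rho of 0.83 and a Pearson r of 0.83 on log10 values. Peaks are not independent replicates, and the list does not give the number of reads behind a score. A MACS score grows with the reads in a peak, so width and score are tied in part by construction. Among the 2392 peaks narrower than 500 bp the median score was 57.8. It was 83.5 for the 11860 peaks from 500 to 1000 bp, 334.3 for the 9996 peaks from 1000 to 2000 bp and 1075 for the 4983 peaks from 2000 to 4000 bp. The 941 peaks of 4000 bp or more had a median score of 2223. These wide peaks were 3.12% of all peaks and held 11.8% of the covered bases.

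**Figure D1:**
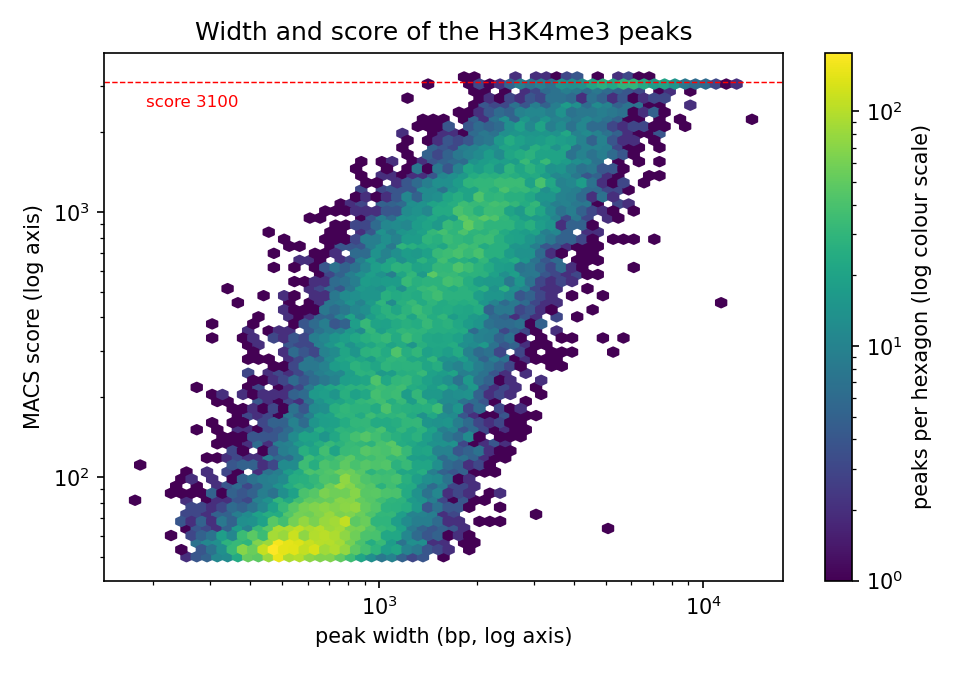
Width of each H3K4me3 peak in bp (horizontal log axis) against its MACS score (vertical log axis), with colour giving the number of peaks per hexagon. Scores rose with width (Spearman rho 0.83 across 30172 peaks), and 230 peaks lie on the dashed line at a score of 3100.

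The widest single peak lay on chromosome 4 at 58119954 to 58134104 and was 14151 bp wide, with a score of 2304. Chromosome 1 held 4 of the 10 widest peaks. These were at 249358030 to 249370756 (12727 bp), 228840290 to 228852969 (12680 bp), 135025157 to 135036870 (11714 bp) and 215573401 to 215584985 (11585 bp). The other 5 were 11146 bp on chromosome 3 at 4506638 to 4517783, 10978 bp on chromosome 4 at 162302548 to 162313525, 10647 bp on chromosome 17 at 7401359 to 7412005, 10526 bp on chromosome 18 at 31537033 to 31547558 and 10493 bp on chromosome 14 at 89024594 to 89035086. A score of 3100 was shared by 8 of the 10. The chromosome 1 peak at 215573401 was the exception at the low end, with a score of 460.8, at the 67.9th percentile of all peaks. In all, 14 peaks were at least 10 kb wide, and their median score was 3100.

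The 10 peaks with the highest listed score were of moderate width, from 1783 to 5910 bp, and none of them was among the 10 widest. Chromosome 10 held 5 of them, at 12937614 to 12941608, 15654375 to 15657531, 16022302 to 16028211, 43967491 to 43971071 and 109603657 to 109609294. The highest value, 3233.06, was shared by 3 peaks, the first 2 of these on chromosome 10 and 1 on chromosome 2 at 218045393 to 218049117. The remaining 4 lay on chromosome 8 at 69834166 to 69837268 (score 3210), chromosome 3 at 11950826 to 11954550 (3208), and chromosome 7 at 115754893 to 115760763 (3183.16) and 67646795 to 67648577 (3183.12). Above 3100 there were 39 peaks, while exactly 3100 was the score of 230 peaks. The next most frequent score was shared by 38 peaks. A score of 3100 may stand in for p-values too small to store, as taken up in the closing observations. The 10 peaks listed here may then not be the strongest, and their widths and chromosomes need not be those of the strongest peaks. Ranking the score of 3100 above all other scores, an alternative chosen after the values were seen, left 0 of these 10 peaks among the highest 10. This outcome was fixed beforehand, because none of the 10 scored 3100 while 230 other peaks did.

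H3K4me3 peaks lay close together in groups far more often than randomly placed peaks did. Another peak was found within 2 kb of 16402 peaks, a share of 54.4% with a Clopper-Pearson interval of 53.8 to 54.9%. In 100 random placements of the same widths within each chromosome span the share was 8.25% on average and ranged from 7.68 to 8.74%. The gaps between neighbours fell into a short and a long class. Of 30151 gaps, 8516 were at most 1 kb, with a median of 215 bp, and 3006 were above 1 kb and up to 5 kb. A further 13744 were above 5 kb and up to 100 kb, and 4885 were above 100 kb.

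**Figure D2:**
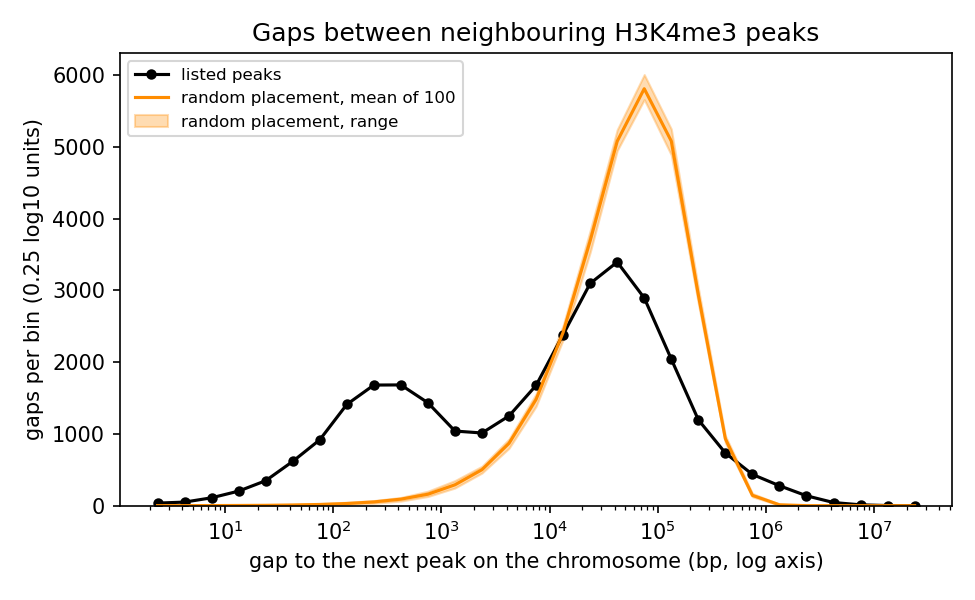
Number of gaps between neighbouring peaks (vertical axis, per bin of 0.25 log10 units) by gap length in bp (horizontal log axis) for the listed peaks (black) and for 100 random placements (orange mean and range). The first bin is not drawn, because it also holds placements that overlapped (531 on average, against 23 listed gaps). The listed peaks show a group of short gaps, with 8516 at most 1 kb, where the drawn random placements have few.

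Joining peaks up to 1 kb apart gave 21656 regions, against 29204 to 29338 in the random placements. A single peak made up 15418 of these regions. There were 4631 regions of 2 peaks, 1170 of 3 peaks and 437 of 4 or more, with 12 peaks at most. Another region lay within 2 kb of 10.9% of the joined regions. Regions of 2 or more peaks were 28.8% of the total, and their best peak had a median score of 738.4, against 118.2 for single peaks. Taking the best of several peaks raises this value by itself, and with scores shuffled among all peaks 100 times the medians averaged 608.8 and 185.5. Over all their peaks, and not the best alone, the regions of 2 or more had a median score of 287.6. Within the regions of 2 peaks the stronger peak had a median score of 657.1 and the weaker 139.1. With the scores of these peaks shuffled among the pairs 100 times, the medians averaged 636.7 and 131.7. Joining raised the largest width from 14151 to 23717 bp. This widest region lay on chromosome 2 at 12256464 to 12280180 and held 7 peaks, of which the peak at 12258109 to 12266202 was 8094 bp wide with a score of 3006. The next was on chromosome 7 at 123665392 to 123688524, 23133 bp wide with 6 peaks. Its peaks at 123665392 to 123672515 and 123672704 to 123679255 both scored 3100. A region on chromosome 18 at 72293282 to 72316224 was 22943 bp wide with 10 peaks, and one on chromosome 3 at 164125506 to 164146641 was 21136 bp wide with 12 peaks. Of the 10 widest single peaks, 1 lay inside the 10 widest joined regions.

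**Figure D3:**
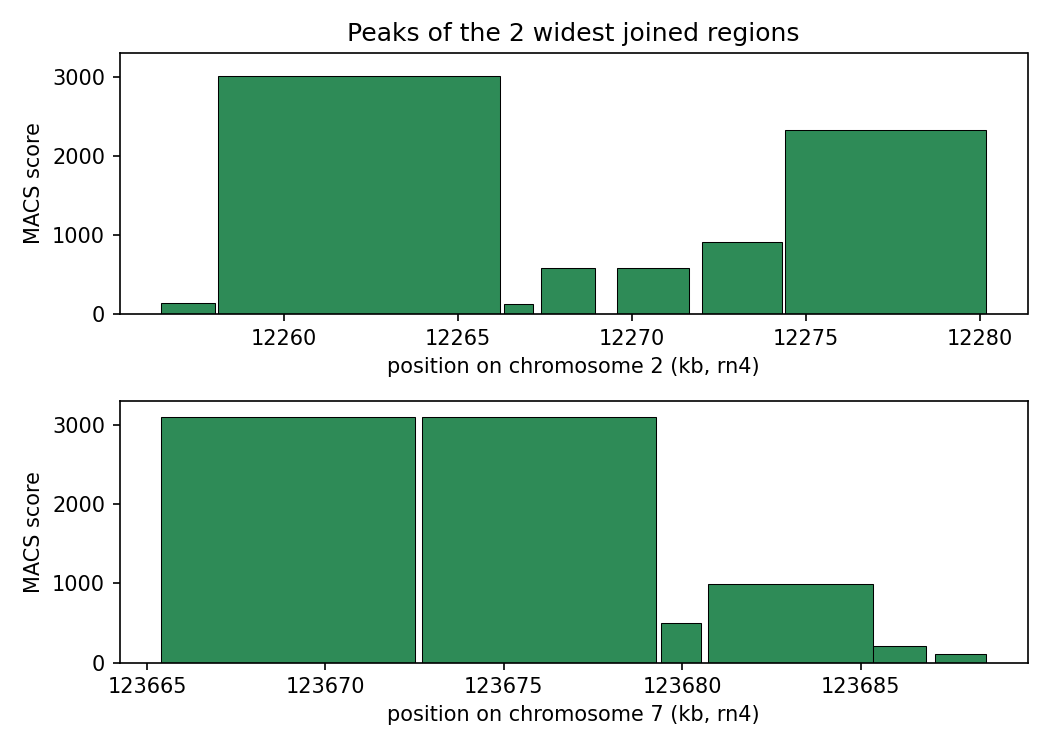
Peaks of the 2 widest joined regions, on chromosome 2 (7 peaks, top) and chromosome 7 (6 peaks, bottom), drawn to scale in kb of rn4, with bar height giving the MACS score of each peak. Wide high-scoring peaks, such as that of score 3006 on chromosome 2 and the pair of score 3100 on chromosome 7, stand beside narrower ones of lower score.

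Chromosomes 12 and 10 were the densest in H3K4me3 peaks, and X the sparsest. Chromosome 12 held 1211 peaks, or 26.0 peaks per Mb of span with a Poisson interval of 24.5 to 27.5. Chromosome 10 held 2486, or 22.6 per Mb with an interval of 21.7 to 23.5. Chromosomes 20 and 19 followed with 16.9 and 16.2 per Mb. The lowest autosomes were chromosome 2, with 7.47 per Mb (interval 7.14 to 7.81), and chromosome 15, with 7.96 per Mb (interval 7.44 to 8.51). X held 629 peaks, or 3.98 per Mb with an interval of 3.68 to 4.31. In relation to its span, X had 0.36 times and chromosome 12 had 2.31 times the number expected from the whole list. The density of chromosome 12 was 6.52 times that of X, with an interval of 5.92 to 7.19. This pair was taken as the highest and lowest density, and the interval does not allow for that choice.

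**Figure D4:**
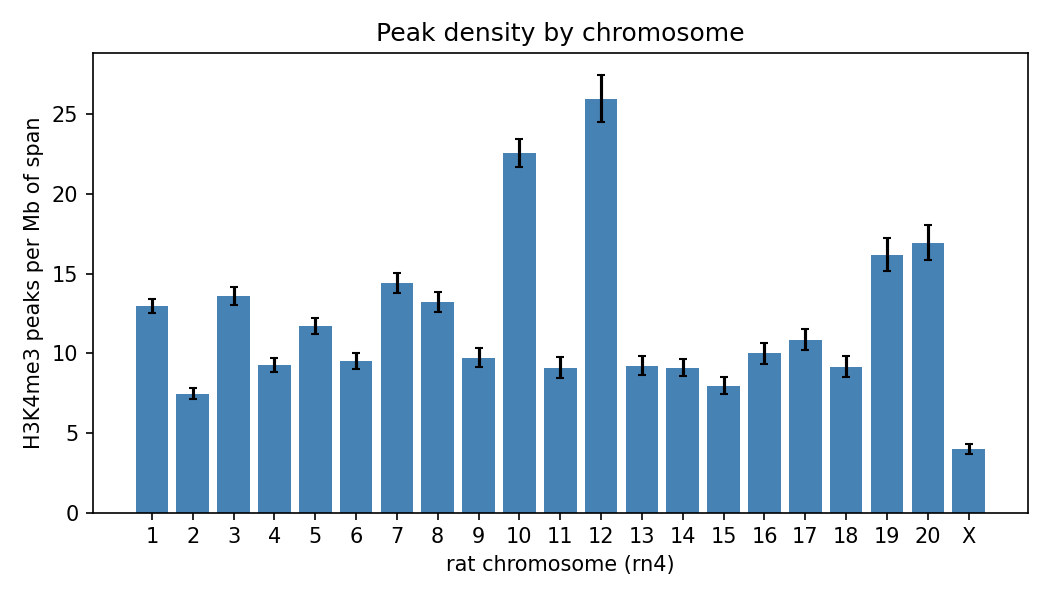
H3K4me3 peaks per Mb of span between the first and last peak (bars, vertical axis from 0) for each rat chromosome, with exact 95% Poisson intervals as error bars. Chromosomes 12 (26.0 per Mb) and 10 (22.6 per Mb) stand highest and X (3.98 per Mb) lowest.

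Peaks were also unevenly spread within chromosomes. The windows and gaps named here were picked by their size after the values were seen. The 1 Mb window with the most peaks, from 10 to 11 Mb of chromosome 7, held 115 peaks that covered 18.6% of its bases. Its neighbour from 11 to 12 Mb held 86. Chromosome 16 from 19 to 20 Mb held 100 peaks, chromosome 1 from 208 to 209 Mb held 87 and chromosome 10 from 86 to 87 Mb held 84. The fullest window in any of 100 random placements held 50 peaks, a number that 69 windows of the list reached or passed. The median window with a peak held 9. The longest stretch without a peak was 19.3 Mb on X, from 101928123 to 121212432. The next were 11.6 Mb on chromosome 2, from 62703912 to 74303311, and 11.5 Mb on chromosome 13, from 19393515 to 30926748. The longest gap in the random placements was 2.79 Mb on X, 1.83 Mb on chromosome 2 and 1.16 Mb on chromosome 13. These placements could fall anywhere in the span, and stretches where no peak could be called were not left out. Chromosome 13 also had no peak before 11.4 Mb, the latest first peak of all chromosomes.

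The peaks of X had a narrower range of scores than those of any autosome, a comparison chosen after the values per chromosome were seen. The 95th percentile of the score was 1041 on X, below the autosomes, which ranged from 1521 on chromosome 13 to 2241 on chromosome 12. The lower quartile was 91.9 on X, above the autosomal range of 66.6 to 83.6. Scores above 1000 were found for 37 of the 629 peaks of X, a share of 5.88% with a Clopper-Pearson interval of 4.18 to 8.02%. The share was 15.3% (interval 14.9 to 15.7%) for the 29543 autosomal peaks. Scores under 100 made up 27.3% of the peaks on X (interval 23.9 to 31.0%) and 35.1% on the autosomes (interval 34.6 to 35.7%). A score of 3100 occurred at 0 of 629 peaks on X, which allows a share of up to 0.477% (3 counts of the total), and at 0.779% of autosomal peaks. By autosome the share ran from 0.229% on chromosome 15 to 1.32% on chromosome 12. Within the limit of X were 3 autosomes, chromosome 17 only just, at 0.476%. The median score, 206.8 on X, lay inside the autosomal range of 141.3 to 227.6. The median width of 951 bp on X lay below the autosomal range of 974 to 1133 bp.

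**Figure D5:**
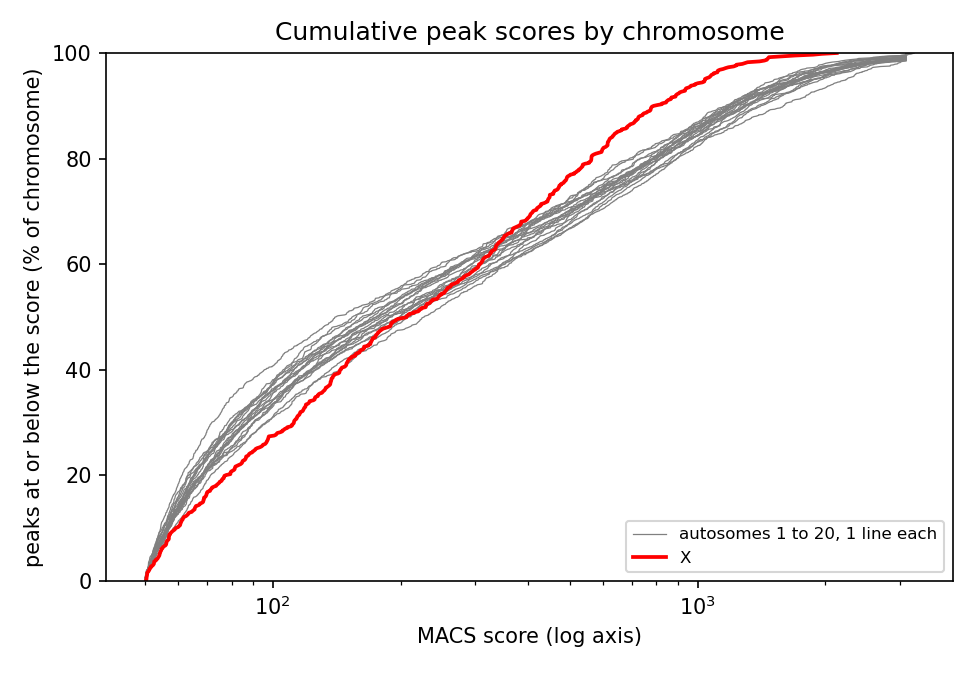
Cumulative percentage of the peaks of a chromosome (vertical axis) at or below a MACS score (horizontal log axis), for X (red) and each of the 20 autosomes (grey). The line of X starts below the autosomes and ends above them, with a lower quartile of 91.9 and a 95th percentile of 1041.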

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

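The comparison of scores on X and its alternatives, the span counted from position 1 and the ranking of the score of 3100 were chosen after seeing the data. The density ratio compared the densest and the sparsest chromosome. Keeping the 15086 peaks at or above the median score raised the median width to 1718 bp, lowered the covered bases to 30.3 Mb, the Spearman rho of width and score to 0.72 and the share of peaks within 2 kb of another to 45.7%. It changed the density ratio of chromosome 12 to X to 5.70 and the 95th percentile score of X to 0.52 of the autosomal one, from 0.59. Joining peaks up to 1 kb apart gave a median width of 1476 bp, 44.7 Mb covered, a rho of 0.87, a density ratio of 7.51 and a largest width of 23717 bp. The share within 2 kb was then 10.9%, since joining removes all gaps up to 1 kb. Peaks at least 500 bp wide had a median width of 1123 bp, covered 41.2 Mb and gave a rho of 0.81. Ranking the score of 3100 above all others kept 0 of the 10 highest-scoring peaks, as it had to, since none scored 3100. The values listed so far were 17 alternatives, and 7 others stayed within the interval of the value, or within 1.5 times for the number of peaks. Covered bases, the largest width and the 10 highest-scoring peaks had no interval, so any change in them counted among the 17. Restricting the list to numbered chromosomes and X removed no peak, so the 6 values under it could not change. A ranking by fold enrichment and all alternatives on transcription start sites and gene lists were not run, because the list gives no fold and gene positions on rn4 were not used here. No paired analysis was possible because there was 1 library. With no read numbers, peaks near the lowest score of 50 cannot be told from background beyond the authors' own threshold.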

Other observations

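All tests in this part were chosen after the results they bear on had been seen. Within regions of 2 joined peaks the stronger peak scored a median of 2.91 times the weaker one, slightly below the 2.94 to 3.19 times of 100 shufflings of the scores among the same pairs. The scores of neighbours up to 1 kb apart had a Spearman rho of -0.03 across 8516 pairs. The rho was 0.07 for the 3006 pairs with a gap above 1 kb and up to 5 kb, 0.12 for the 10155 pairs above 5 kb and up to 50 kb, and 0.05 for the 8474 pairs further apart. Peaks are not independent replicates, so these values describe the list only. A region on chromosome 5 at 118160977 to 118178928 joined 9 peaks over 17952 bp, yet its best score was 582.3. The other 9 of the 10 widest joined regions had best scores above 2000.

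The first pattern is the narrow spread of scores on X. Of the 16983 overlapping stretches of 629 consecutive autosomal peaks, 0 had a 95th percentile score as low as that of X (1041). The lowest was 1452. The stretches share most of their peaks and reuse a measure by which X had stood out, so their number is no measure of support. A candidate explanation is that scores on X are lower by 1 constant factor. Autosomal scores multiplied by 0.46, with values under the lowest listed score dropped, came within 8.13% of X at the 5 percentiles used to choose the factor, so the match is no independent check. The scaled scores lay above X at the lower quartile and median and below it at the 3 higher percentiles, so the shapes differed somewhat. Over 100 resamplings of the peaks of X the central 95% of the factors lay between 0.38 and 0.57. The autosomes, each fitted against the others with a factor of at most 1, gave 0.85 to 1. A single copy of X or poorer mapping of reads to it may lower scores, but the score is not proportional to signal, and neither copy number, mappability nor their effect on the score was tested. The factor alone would leave 7.28 peaks per Mb at the pooled autosomal density against the observed 3.98, a difference that cannot be told apart from fewer H3K4me3 sites on X. Single autosomes ran from 7.47 to 26.0 peaks per Mb, and neither this spread nor the error of the factor is carried into the 7.28.

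The second pattern is the shared score of 3100, which lies below 39 other scores. If a p-value too small for a double-precision number had been replaced by a fixed score, these 230 peaks would be the strongest of the list. Their median width was 5910 bp, against 4332 bp for the 126 other peaks scoring 2900 or more. The difference of 1578 bp had a two-sided permutation p of 1e-05, the smallest that 100000 resamples can give. The permutation treated single peaks as units. Peaks are not independent replicates, so this p-value describes the list only and is no measure of repeatability. The widths go with this technical explanation, under which the 10 highest listed scores are not the 10 strongest peaks. They do not settle it, because the comparison peaks include scores from 2900 to below 3100. Width rose with score across peaks, so narrower comparison peaks could also arise if 3100 were a true score. The design gives no biological explanation to set against it.

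The third pattern is the closeness of peaks. Uneven density at the scale of 1 Mb or 100 kb windows does not account for it alone. With each peak placed at random inside its own 1 Mb window, at most 16.3% lay within 2 kb of another in 100 placements. A second set of 100 gave at most 16.4%. Inside its own 100 kb window the highest share was 22.7%, against 54.4% observed. The share rose as the window shrank, and unevenness on scales below 100 kb was not tested. One hypothesis is that both sides of a nucleosome-free stretch at a promoter were called as separate peaks, which would favour one gap length. The fullest 50 bp bin of gaps began at 0 bp with 1208 gaps, and the bins fell steadily to 321 gaps from 450 to 500 bp. Because the caller may extend reads and so shorten every gap by an unknown amount, this value of 0 leaves open both that hypothesis and a splitting of single domains where the signal dipped under the threshold.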
